A study of Mus musculus with 14 samples.

How the data were processed

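RNA of the hippocampal CA3 field was measured in adult mice of the Sv129Pas strain, wild type (WT) or mutant for Dcx, the X-linked gene of the microtubule-binding protein doublecortin. CA3 was taken in 1 piece from 5 WT mice. In Dcx mutants its pyramidal cells lie in 2 layers, which were dissected apart, giving an outer layer (SPE) from 5 mice and an inner layer (SPI) from 4 of the same 5. Per the labels' protocols, total RNA came from dissected pieces that were pooled, was purified with a column kit for small amounts, and was amplified and biotin-labelled for Illumina bead arrays. Each of the 14 samples was hybridised to 1 array. The titles name 1 animal per sample, so the 10 animals were taken as the biological replicates. The sample titles call the layers inner and outer and were used for the grouping; the bracketed layer code in the brain region field of the outer samples, and in the source field of 1 of them (animal 147), is the inner layer's, against the title and the words of the same fields.

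The authors deposited 2 tables of the same arrays. In the first, which carries no normalisation between arrays, each of 25697 probes has a bead signal on a linear intensity scale and a detection p-value per array. BeadStudio is named in the submitters' processing notes, with no version; how it handled background is not given in the sources used here. The lowest signal per array was 71.3 to 88.6 and no value lay below 0, so background had not been subtracted to 0. The deposited detection p-value came in steps of 1 in 798 negative controls. The second deposited table holds normalised intensity values: its columns kept the rank of the probes within each array (Spearman correlation above 0.99 on every array), shared 1 distribution with medians of 104, and were on the linear scale, so they were taken as quantile-normalised without background subtraction or centring. Neither table has sample columns outside these 14 samples.

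Values were computed from the first table with R 4.3.3 and limma 3.58.1. Background was corrected with neqc (normexp, with negative-control moments inferred from the detection p-values, offset 16), followed by quantile normalisation and log2. Probes with a detection p under 0.05 on at least 4 arrays were kept (12140). Platform annotation gave 1 gene symbol for 23978 probes, several for 0 and none for 1719; 23962 named probes matched a RefSeq mouse gene table (assembly GRCm38.p6, used for names only) by Entrez identifier, and 0 symbols changed. The probe with the highest mean stood for each gene, leaving 9355 features, 8671 of them named genes and 684 unnamed probes. Of the genes, 2085 had further probes past the filter.

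All 14 arrays entered 1 limma fit with the 3 groups. Animals 146, 147, 148 and 166 gave both layers, so the animal was a random block (consensus correlation 0.319, 11 residual and 4.11 prior degrees of freedom). The pairing comes from the animal numbers in the titles. The deviations of same-animal layers from their group means correlated at 0.119, 0.287, 0.323 and 0.631 for animals 147, 146, 166 and 148. The highest correlation of each inner layer with another animal's outer layer was lower (0.0723, 0.271, 0.315 and -0.332). Outer layers were not set against other animals' inner layers in turn. The 0.315 of animal 166 lay above the same-animal values of 147 and 146, so this check of the pairing is weak. Contrasts were SPI vs WT, SPE vs WT, the mean of both layers against WT (KO vs WT) and SPI vs SPE. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 9355 features. Errors of log2 differences are the fit's standard errors (SE), and group levels are means with SD of normalised log2 signal. A probe not detected on any array of a group has only a bound there.

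Before the data were examined, 41 gene lists were fixed (organelles, mitochondrial and synaptic functions, stress programmes, and markers of hippocampal and other cell types). The 39 lists with at least 4 measured genes were tested with camera at a preset inter-gene correlation of 0.01, on data and design adjusted for the animal correlation. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it, each adjusted over the 39 lists. The genes named in the text were also chosen by a rule fixed before the data were examined: per comparison the 8 largest rises and 8 largest falls among called genes outside the sex-linked list, or the 8 smallest p-values where fewer were called; up to 3 measured members of each list with the smallest p; and all measured doublecortin family and sex-linked genes. The text gives a selection of these. The groups, designs and lists were fixed at the same time.

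The other settings fixed at that time were no background correction, median scaling in place of quantile normalisation, the deposited normalised values, 3 other detection filters, all probes as features or the mean of a gene's probes, no block, the animal as a fixed block, 2-group fits, layer means per animal, array weights, an intensity trend with robust moderation, and leaving out each array. A chip term was not run, since no file names the chip. After the data were seen, 3 were added: leaving out the 3 arrays of lowest mean signal, leaving out animal 148, and the log2 mean raw signal of each array as a covariate.

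The statistics were tested on simulated data built from the real WT means and the spreads of the fit, with 2 draws of 9355 features per comparison. Changes of 0.5, 1 or 2 on the log2 scale were added to some features, and each percentage below is of 134 changed features. With spread unequal between arrays as measured, simulated 2-fold changes were called for 70.1% of genes in SPI vs WT, 84.3% in SPE vs WT, 77.6% in KO vs WT and 82.8% in SPI vs SPE. Simulated changes of 0.5 on the log2 scale were called for 9.70%, 14.9%, 17.2% and 28.4% in the same order. A simulated rise of 0.5 in a list of 19 genes was called, with 0 of the other lists. The simulated genes were independent of each other and spread was equal between arrays. False list calls from correlated genes could therefore not appear, while the estimated correlation of that list in the real data was 0.203. Precision is limited by the number of arrays: at the median feature the 95% confidence interval of a log2 difference reached 0.34, 0.33, 0.30 and 0.29 to either side in that order. Plots were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.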

Results

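Gene expression in hippocampal CA3 was profiled on 14 bead arrays, 5 from undivided WT tissue, 5 from the outer (SPE) and 4 from the inner (SPI) pyramidal layer of Dcx mutant mice. The study's title concerns the Golgi apparatus and mitochondria of mutant pyramidal cells, and the design asks how each layer differs from WT CA3. Mean raw signal was 456 ± 54.1 intensity units (SD, n = 5) in WT, 411 ± 82.2 (n = 5) in SPE and 261 ± 110 (n = 4) in SPI. SPI lay below WT (two-sided exact permutation test, p = 0.00794), while the test gave p = 0.373 for SPE against WT. In all 4 mice with both layers SPI was the dimmer one (SPI minus SPE -132 ± 119 units, SD), with p = 0.125 in a two-sided exact paired permutation test, the smallest that 4 pairs allow. The dimmest arrays were SPI 147 at 119, SPI 148 at 231 and SPE 148 at 279. Detected probes numbered 11618 ± 286 in WT, 11225 ± 697 in SPE and 10324 ± 1347 in SPI, with 8413 on SPI 147. The first principal component held 46.4% of the variance and placed the SPI arrays between 8.48 and 46.3, SPE 148 at 19.3 and every other SPE and WT array below 0.

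**Figure D1:**
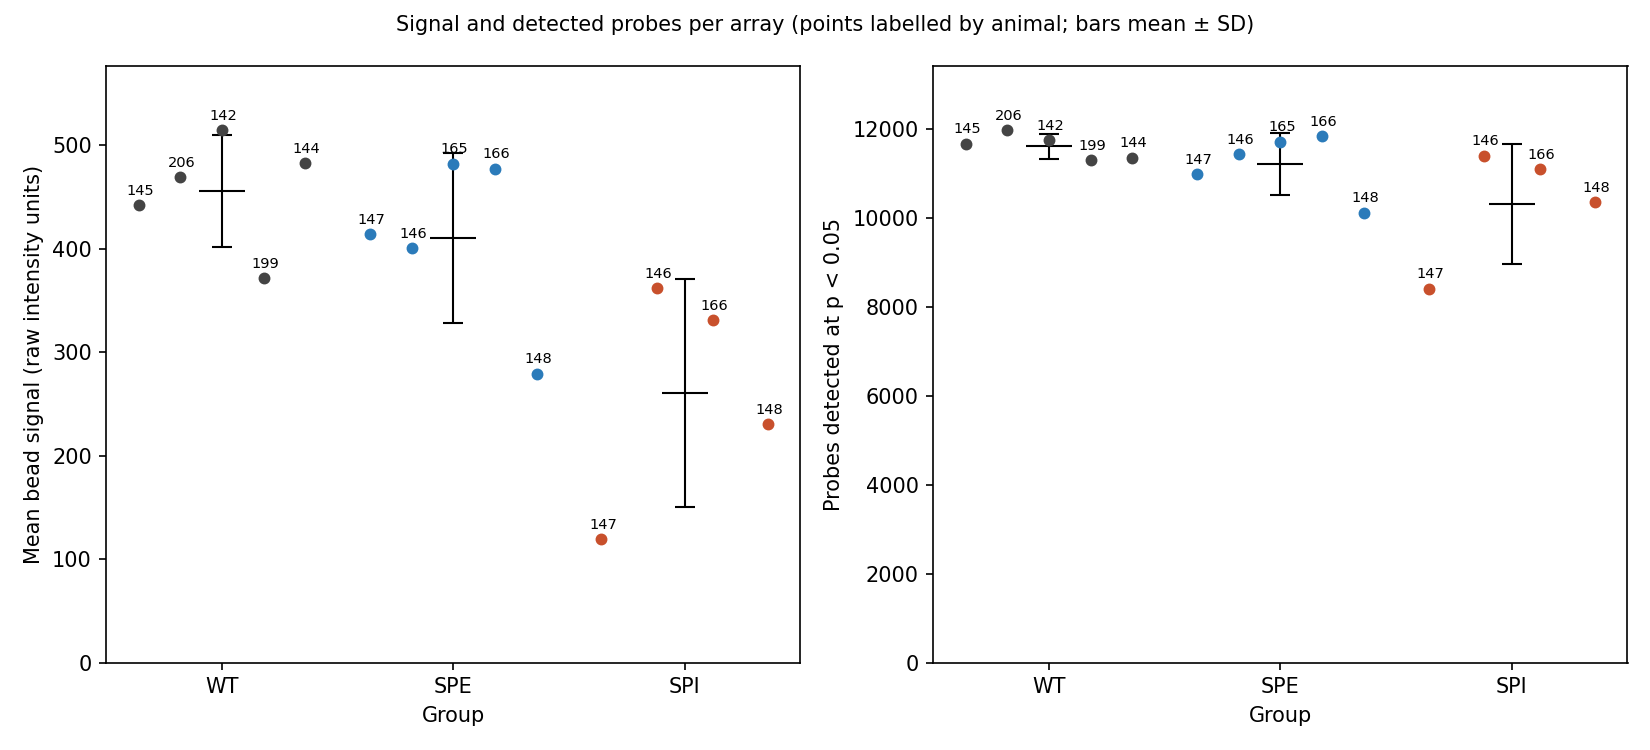
Mean raw bead signal (left, intensity units) and number of detected probes (right) for each array, with points labelled by animal number and bars giving group mean ± SD. SPI 147 was lowest in both, at 119 units and 8413 probes.

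Dcx itself, the mutated gene, was read by a dim probe. Its log2 signal was 5.92, 5.92, 5.50, 5.50 and 5.91 in WT mice 145, 206, 142, 199 and 144. It was 5.37, 5.07, 5.57, 4.85 and 5.79 in SPE of mice 147, 146, 165, 166 and 148, and 4.64, 5.64, 5.37 and 5.55 in SPI of mice 147, 146, 166 and 148. The differences from WT were -0.43 ± 0.23 (SE) in SPI (limma adjusted p = 0.184) and -0.42 ± 0.22 in SPE (adjusted p = 0.904), and neither passed. The SPI difference turned to 0.21 with median scaling. The labels do not say which part of the gene was mutated, so this probe checks nothing about the genotype. Among the related doublecortin-like kinases, Dclk3 rose in SPI by 0.84 ± 0.17 (adjusted p = 0.00406) and Dclk1 by 0.38 ± 0.13 (adjusted p = 0.0440). The Dclk1 call was lost without the animal block and without any 1 of WT 145, 206, 142 and 199, SPE 147, 146 and 166, and SPI 146 and 148. The Dclk3 call was lost with the mean signal as a covariate. Dclk2 differed by 0.19 ± 0.13 (adjusted p = 0.284). In SPE, Dclk1, Dclk2 and Dclk3 differed from WT by 0.24 ± 0.12, 0.16 ± 0.12 and 0.013 ± 0.165, none past the threshold. Over the 4 members of the family, 2 rose in SPI, both over all genes and adjusted over the list alone. The sex-linked genes Eif2s3y (0.15 ± 0.39 in SPI and 0.41 ± 0.36 in SPE) and Uty (-0.32 ± 0.22 and -0.0041 ± 0.212) did not pass in either layer, although with median scaling Eif2s3y was called higher in SPI, by 0.71. Both were lowest on SPI 147, Eif2s3y at 4.36 and Uty at 4.26, against 6.04 and 5.37 in SPE of the same mouse. Without that array the Eif2s3y difference in SPI was 0.65.

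The largest rises in the inner layer of the mutants over WT CA3 were in Cort, a neuropeptide of interneurons (2.29 ± 0.21 on the log2 scale, 4.88-fold, SPI n = 4, WT n = 5), Slc17a8, the vesicular glutamate transporter VGLUT3 (2.19 ± 0.19), the matrix protein gene Matn4 (2.08 ± 0.23), Erich5 (2.08 ± 0.45), neuropeptide Y, Npy (1.99 ± 0.20), Pdgfra, a marker of oligodendrocyte precursors (1.85 ± 0.16), the transcription factor gene St18 (1.85 ± 0.27) and Rgs10, a regulator of G protein signalling (1.83 ± 0.18). For each of these 8 genes all 4 SPI arrays lay above all 5 WT arrays, and limma's adjusted p ran from 9.87e-06 for Pdgfra to 0.00516 for Erich5, whose call was lost with the mean signal as a covariate.

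Markers of 5 cell types stood higher as lists in SPI than in WT by camera with a preset inter-gene correlation. None of these calls held with an estimated correlation: the adjusted p was then 0.244 for myelin and interneurons and 0.221 for the astrocyte, microglia and precursor lists. Of 22 measured myelin and oligodendrocyte markers 15 rose, 0 fell and 7 did not pass, among them Enpp6 (1.58 ± 0.18), the transcription factor Olig1 (1.44 ± 0.16) and the myelin enzyme Cnp (1.34 ± 0.16), and the median over the list was 1.01. Of 19 astrocyte markers 11 rose, with Gja1, the gap junction protein connexin 43, at 1.54 ± 0.17, the claudin Cldn10 at 1.30 ± 0.11 (1 of its 2 other probes had the opposite sign) and the glutamate transporter Slc1a3 at 1.15 ± 0.12 (list median 0.70). Microglia markers rose for 10 of 15, with Laptm5 at 1.51 ± 0.19, the complement gene C1qa at 1.24 ± 0.17 and Tmem119 at 1.02 ± 0.13 (list median 0.91). Of 8 oligodendrocyte precursor markers 4 rose and 0 fell (median 0.67). Among 15 interneuron markers 7 rose, including the neuropeptide Sst (1.24 ± 0.14) and the calcium-binding protein Pvalb (1.04 ± 0.12), and 2 fell, Cck (-0.39 ± 0.13, adjusted p = 0.0360) and Nos1 (-0.69 ± 0.23, adjusted p = 0.0415), which were picked out after their values were seen (list median 0.82). Both calls were lost with array weights, with the mean signal as a covariate, with median scaling (Nos1 then at 0.11) and without the 3 dimmest arrays. The Cck call was also lost in the fit of SPI and WT alone and without any 1 of WT 145, 206, 142 and 199 and SPI 147 and 148. That of Nos1 was also lost without background correction, with the deposited normalised values, without a detection filter and without any 1 of WT 206, 142, 199 and 144, SPE 147 and 166, and SPI 147 and 148. Camera's adjusted p was 8.24e-08 for the myelin and the astrocyte list, 2.03e-06 for microglia, 0.000979 for interneurons and 0.00643 for oligodendrocyte precursors. Fry's adjusted p was at most 0.00039. Adjusted over the list alone, rises numbered 15, 12, 11, 10 and 4 for myelin, astrocyte, microglia, interneuron and precursor markers, and 2 interneuron markers fell. Over the members of these lists the median in SPE was 0.023 above WT.

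Other cell markers moved less or in both directions. Of 20 endothelial and mural markers 4 rose and 1 fell, with Vtn at 0.94 ± 0.14 and Itm2a at -1.20 ± 0.20 (list median 0.28, camera adjusted p = 0.184). The CA1 pyramidal markers Pou3f1 (1.07 ± 0.23, a call lost with the mean signal as a covariate) and Mpped1 (0.84 ± 0.11) rose, 2 of 6 measured (median 0.52, adjusted p = 0.184 with camera and 0.00450 with fry). Of 9 CA3 pyramidal markers 2 rose and 1, Cpne4, fell (-0.91 ± 0.21, also lost with that covariate). Pan-neuronal markers gave 2 rises and 7 falls among 23 (median -0.14, adjusted p = 0.184 with camera and 0.0200 with fry). The reelin gene Reln, expressed by Cajal-Retzius cells and interneurons, rose by 1.61 ± 0.23, within a list on reelin signalling and migration in which 7 of 24 rose and 7 fell.

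**Figure D2:**
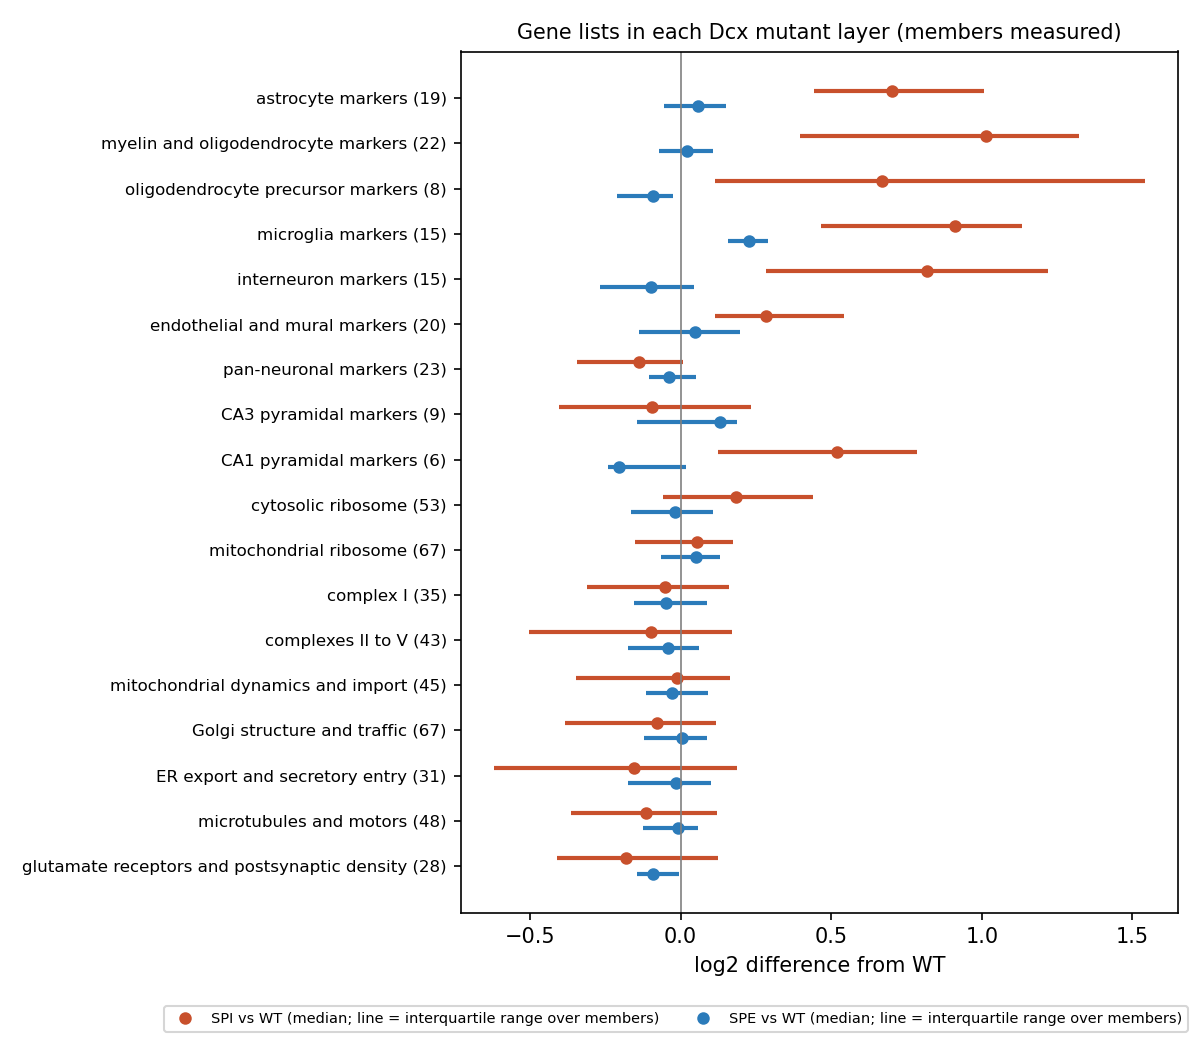
Median log2 difference from WT (points) with the interquartile range over list members (lines) for selected gene lists in SPI (orange) and SPE (blue), with the number of measured members in brackets. In SPI the medians of the 5 glial and interneuron lists lay between 0.67 and 1.01, and in SPE between -0.099 and 0.23.

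The genes with the largest falls in SPI were Tspan3, a tetraspanin (-2.67 ± 0.49, 6.37-fold), Tceal3 (-2.43 ± 0.39), Atp5pb, a subunit of mitochondrial ATP synthase (-2.35 ± 0.41), the selenoprotein gene Selenof of the endoplasmic reticulum (-2.30 ± 0.44), the RNA-binding proteins Hnrnpa2b1 (-2.28 ± 0.39) and Rbm3 (-2.15 ± 0.35), the ubiquitin-conjugating enzyme Ube2e3 (-2.12 ± 0.45) and the transcription regulator Tsc22d1 (-2.10 ± 0.49). The adjusted p ran from 0.000898 to 0.00724. Levels of these genes varied widely among SPI arrays: Tspan3 was at 10.06 ± 0.18 (SD) in WT and 7.35 ± 1.29 in SPI. SPE 148, the dimmest SPE array, had the lowest SPE level of each of these 8 genes, with Tspan3 at 7.91 there. The calls of Ube2e3 and Tsc22d1 were lost with the mean signal of the array as a covariate.

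Genes of mitochondria and the secretory pathway changed in both directions. Over all 9355 features 24.5% were called in SPI vs WT, 1273 higher and 1016 lower, and the counts per list are to be read against that share. Of 67 Golgi genes 7 rose and 11 fell, among them the SNARE Gosr2 (-1.09 ± 0.22, with only 1 of its 3 other probes of the same sign), Golga7 (-0.93 ± 0.20) and the sulphotransferase Tpst2 (0.61 ± 0.12). Of 31 genes of export from the endoplasmic reticulum 1 rose and 8 fell, with Kdelr2, a retrieval receptor, at -1.12 ± 0.26 and Mcfd2 at -0.75 ± 0.13. Complexes II to V gave 4 rises and 7 falls among 43, with Cox7a2l at -1.41 ± 0.26, and complex I 3 rises and 5 falls among 35, with Ndufs3 at -0.81 ± 0.15. In the citrate cycle list 0 of 19 rose and 4 fell, including Pdhb of pyruvate dehydrogenase (-1.71 ± 0.29). Of 45 genes of mitochondrial dynamics and import 4 rose and 10 fell: the outer membrane channel Vdac3 was at -1.48 ± 0.27, the fission GTPase Dnm1l at -0.65 ± 0.15 and the transport GTPase Rhot2 at 0.39 ± 0.09 (1 of its 2 other probes disagreed in sign). The mitochondrial ribosome gave 4 rises and 9 falls among 67, with Mrpl18 at -1.67 ± 0.34. Microtubule and motor genes gave 4 rises and 13 falls among 48, such as the dynein light chain Dynll2 (-1.40 ± 0.25), the tubulin Tuba1a (-1.28 ± 0.26) and the kinesin Kif2a (-0.70 ± 0.17). Cytosolic ribosome genes gave 17 rises and 4 falls among 53, with Rpl36a at 0.69 ± 0.13. Adjusted over the list alone, the Golgi list had 7 rises and 11 falls, microtubules 4 and 14, and complexes II to V 6 and 7.

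None of these organelle lists passed camera in SPI vs WT. The median and camera's adjusted p were -0.079 and 0.182 for the Golgi, -0.15 and 0.146 for export, -0.051 and 0.444 for complex I, -0.099 and 0.265 for complexes II to V, -0.013 and 0.383 for mitochondrial dynamics, -0.12 and 0.117 for microtubules, and 0.18 and 0.0804 for the cytosolic ribosome. The citrate cycle (median 0.017, mean -0.12, adjusted p = 0.543) and mitochondrial ribosome (median 0.055, mean -0.058, adjusted p = 0.543) had a median above 0 and a mean and test statistic below it. Fry, which asks only whether a list's genes moved on balance one way, passed the Golgi (adjusted p = 0.0126), export (0.00259), microtubules (0.0126) and mitochondrial dynamics (0.0418) as lower and the cytosolic ribosome (0.00169) as higher. It gave 0.204 for complexes II to V, 0.534 for complex I, 0.0940 for the citrate cycle and 0.593 for the mitochondrial ribosome. With median scaling the Golgi, mitochondrial dynamics and microtubule lists passed camera as lower, at adjusted p = 0.000261, 0.00444 and 0.00444. Microtubules also passed with the mean of a gene's probes (0.00717) and without SPI 147 (0.0380). These calls used the preset correlation. With an estimated correlation the main fit gave camera adjusted p = 0.244 for the Golgi, 0.393 for mitochondrial dynamics and 0.393 for microtubules. The calls of Golga7, Tpst2, Kdelr2 and Rhot2 were lost with median scaling and with the mean signal as a covariate, those of Gosr2, Ndufs3, Dnm1l, Mrpl18, Dynll2, Tuba1a and Kif2a with that covariate only, and that of Rpl36a with median scaling. Among voltage-gated channels 7 of 41 rose and 8 fell, including Kcnip2 (-1.61 ± 0.26) and Kcnq5 (-1.54 ± 0.24).

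In all, limma called 2289 of 9355 features in SPI vs WT, 1273 higher and 1016 lower, and 497 of them differed by more than 2-fold. SPI and WT arrays did not overlap for 2009 features (21.5%), where chance gives 1.59%. For 44 of the called features 1 of the groups had no array above detection. Median scaling moved the median of all features to 0.18 in SPI vs WT, against 0.035 with quantile normalisation, and gave 2469 higher and 722 lower calls. With every probe as a feature the balance turned, to 1402 higher and 1770 lower calls of 12140 probes. Of the genes called higher, 321 had further probes, whose median difference was 0.08 against 0.56 for the brightest probes, with the same sign for 55.5%, against 57.7% for genes not called. Of those called lower, 276 had further probes, at -0.55 against -0.74, with the same sign for 87.0%. Over all genes the 2785 further probes had a median of -0.23, and brightest probes of similar level one of 0.025. For the 17 members of the 5 glial and interneuron lists with further probes, these had a median of 0.17 against 0.74, with the same sign for 76.5%. With log2 mean signal as a covariate, which was itself lower in SPI, 503 features were called, 383 higher and 120 lower.

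**Figure D3:**
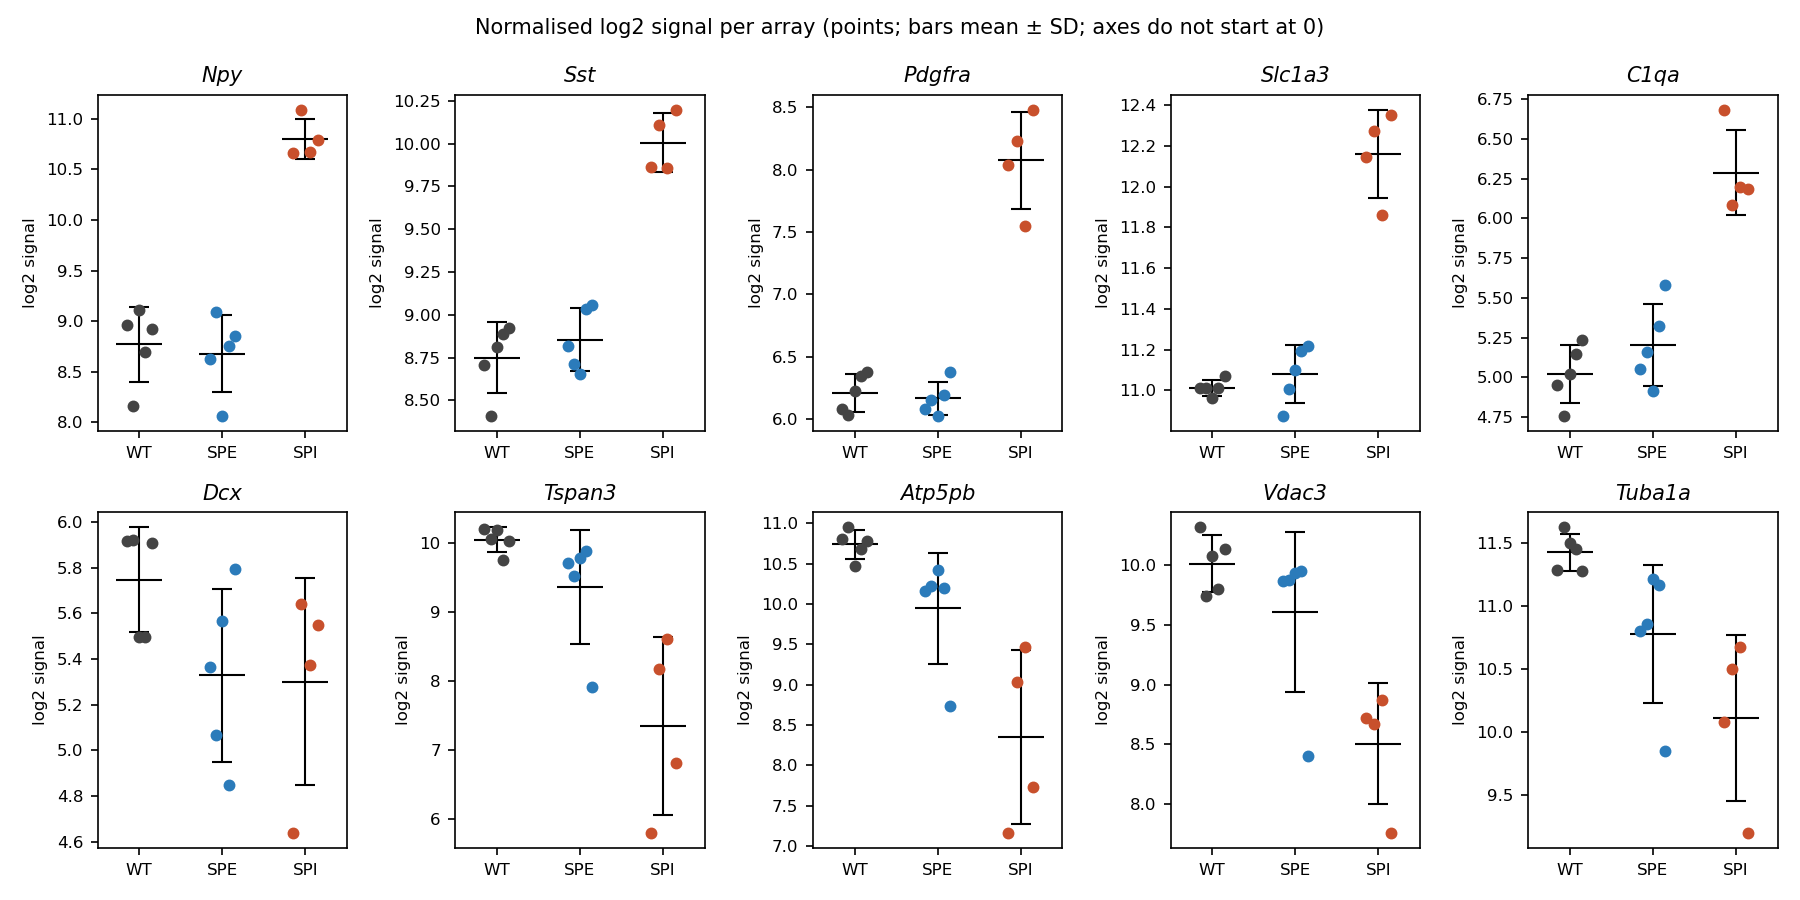
Normalised log2 signal on each array (points) with group mean ± SD (bars) for 10 genes, by group (WT n = 5, SPE n = 5, SPI n = 4); the vertical axes do not start at 0. Npy, Sst, Pdgfra, Slc1a3 and C1qa were higher on every SPI array than on any other array, and the lowest SPE points for Tspan3 (7.91), Atp5pb (8.73) and Vdac3 (8.40) are SPE 148.

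No gene was called between the outer layer and WT. Limma called 0 of 9355 features in SPE vs WT (smallest adjusted p = 0.904), with 358 at an unadjusted p under 0.05 where 468 would be expected by chance, and each alternative fit in limma also called 0. Over the 9355 features that count was 826 with the SPE and WT arrays alone, 722 with array weights and 205 with median scaling. It was 147 of 9312 features without SPE 148, 223 of 9241 without WT 206 and 599 of 9334 without SPI 147. Among the smallest p-values were those of the urea cycle enzyme Asl (-0.54 ± 0.13), the clock gene Arntl (0.49 ± 0.12), the autophagy protein gene Map1lc3b (0.49 ± 0.13), the synaptic organiser Cbln1 (-0.44 ± 0.11), the ceramide synthase Cers1 (-0.63 ± 0.17), Sez6 (-0.39 ± 0.11) and Lypd1 (-1.14 ± 0.32), none past the threshold (adjusted p = 0.904). Ybx3 was not detected on any SPE array and its level in WT was at least 1.05-fold higher (adjusted p = 0.904). Groups did not overlap for 152 features (1.62%), where chance gives 0.794%.

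Of the gene lists, microglia markers stood higher in SPE than in WT (median 0.23), and complexes II to V (median -0.043) and glutamate receptors with postsynaptic density genes (median -0.092) stood lower, each at a camera adjusted p of 0.0412 and with 0 members called, also when adjusted over the list alone. The adjusted p was 0.467 with an estimated correlation and 0.693 with fry for all 3. Values of microglial genes were 0.38 ± 0.15 for P2ry13, 0.31 ± 0.12 for Tmem119 and 0.30 ± 0.18 for Laptm5. Golgi genes had a median of 0.0054 (camera adjusted p = 0.605), complex I -0.050 (0.173), mitochondrial dynamics -0.028 (0.271) and microtubules -0.0073 (0.271). The microglia call was lost without background correction (0.139), with the deposited normalised values (0.140) and without WT 206 (0.0997), WT 142 (0.0836), WT 144 (0.112), SPE 147 (0.194), SPE 166 (0.180) or SPI 148 (0.0539). The complexes call was lost with median scaling (0.348, where the list median was 0.071), with the mean of a gene's probes (0.0942) and without WT 142 (0.0836), WT 199 (0.148), WT 144 (0.103), SPE 146 (0.0612), SPE 166 (0.113) or SPI 148 (0.0539). The glutamate receptor call was lost with median scaling (0.114), with the mean of a gene's probes (0.0613) and without WT 142 (0.0836), WT 144 (0.113), SPE 147 (0.228), SPE 146 (0.0551), SPE 148 (0.117), SPI 148 (0.0539), animal 148 (0.202) or the 3 dimmest arrays (0.244).

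The layers of the mutants were also set against each other. The largest rises in SPI over SPE were in Lypd1, a modulator of nicotinic receptors (2.58 ± 0.29, 6.00-fold, SPI n = 4, SPE n = 5), Cort (2.35 ± 0.17), Matn4 (2.11 ± 0.20), the cadherin Cdh13 (2.10 ± 0.18), Npy (2.08 ± 0.17), St18 (2.03 ± 0.23), Slc17a8 (1.99 ± 0.16) and Cbln1 (1.93 ± 0.10), with adjusted p from 5.16e-08 to 2.88e-05, and for each all SPI arrays lay above all SPE arrays. The largest falls were in Tspan3 (-1.98 ± 0.41), Hnrnpa2b1 (-1.95 ± 0.33), Selenof (-1.80 ± 0.37), Tspyl1 (-1.73 ± 0.29), Tceal3 (-1.66 ± 0.33), Gm5643 (-1.63 ± 0.34), the phosphatase subunit Ppp1cb (-1.61 ± 0.31) and Efr3a (-1.58 ± 0.39). The calls of Tspan3, Selenof, Tceal3 and Efr3a were lost with the animal as a fixed block, those of Tceal3, Gm5643 and Efr3a with the mean signal as a covariate, and those of Gm5643 and Ppp1cb with median scaling. Those of Ppp1cb and Efr3a were lost without the 3 dimmest arrays, and that of Efr3a also without SPI 148 and without a detection filter.

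By list, 10 of 15 interneuron markers rose in SPI over SPE (median 1.13), with the vesicular GABA transporter Slc32a1 at 1.65 ± 0.16 and Pvalb at 1.41 ± 0.11. Of myelin and oligodendrocyte markers 15 of 22 rose (median 0.89, Enpp6 at 1.65 ± 0.16), of precursor markers 5 of 8 (median 0.82, Pdgfra at 1.89 ± 0.13), of astrocyte markers 13 of 19 (median 0.66, Slc1a3 at 1.08 ± 0.10) and of microglia markers 9 of 15 (median 0.63, C1qa at 1.06 ± 0.14), and 0 fell in any of these lists. Camera's adjusted p was 2.99e-06 for interneurons, 1.42e-11 for myelin, 6.13e-06 for precursors, 2.11e-10 for astrocytes and 2.99e-06 for microglia. With an estimated correlation the adjusted p was 0.0956, 0.102, 0.0598, 0.0956 and 0.102, so no call held. Adjusted over the list alone, rises numbered 11, 16, 6, 14 and 10, and 2 interneuron markers fell. Cytosolic ribosome genes rose for 16 of 53, with Rps19 at 0.56 ± 0.09 (its other probe had the opposite sign) and Rpl37 at 0.46 ± 0.09 (list median 0.23, camera adjusted p = 9.1e-05, and adjusted p = 0.102 with an estimated correlation). That list call was lost with median scaling (0.580). Thalamic markers rose for 3 of 6, with Slc17a6, the glutamate transporter VGLUT2, at 0.89 ± 0.22 and the transcription factor Tcf7l2 at 0.66 ± 0.16 (median 0.64, camera adjusted p = 0.0301, and adjusted p = 0.102 with an estimated correlation), and the list call was lost without SPI 146 (0.0886), SPI 166 (0.0674) or SPE 148 (0.111).

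The CA1 markers Pou3f1 (1.35 ± 0.19) and Mpped1 (1.06 ± 0.09) rose in SPI over SPE, as did Reln (1.36 ± 0.19) and Dclk3 (0.83 ± 0.15). Of 9 CA3 markers 2 rose, St18 (2.03 ± 0.23) among them, and 2 fell, Nectin3 (-0.60 ± 0.12) among them (median -0.18, camera adjusted p = 0.768). The potassium channel Kcnq5 (-1.45 ± 0.20) and Golga7 (-0.93 ± 0.17) also fell. The calls of Nectin3, Rpl37, Slc17a6 and Tcf7l2 were lost with the animal as a fixed block, those of Golga7 and Rpl37 with median scaling, those of Nectin3 and Tcf7l2 with the mean signal as a covariate, those of Nectin3 and Rpl37 without the 3 dimmest arrays, and that of Slc17a6 without SPI 148. Golgi genes gave 3 rises and 8 falls among 67 (median -0.090, adjusted p = 0.193 with camera and 0.00206 with fry), and mitochondrial dynamics 3 rises and 6 falls among 45 (median -0.0057, adjusted p = 0.669 with camera and 0.0962 with fry).

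Limma called 1917 features in SPI vs SPE, 1014 higher and 903 lower, with 298 beyond 2-fold, and because both layers were set against the same WT arrays this is also the test of whether their differences from WT differed. Arrays of the layers did not overlap for 935 features (9.99%). Chance gives 1.59% if all these arrays are taken as independent, which ignores that 4 mice gave both layers. For 36 called features 1 of the layers had no array above detection. Median scaling gave 1538 higher and 598 lower calls, and every probe as a feature 1157 higher and 1480 lower. The count fell to 1065 without the animal block, 356 with the animal as a fixed block in the 4 mice with both layers, 452 with the arrays of these groups alone, 946 without SPI 148, and 781 (599 higher, 182 lower) with the mean signal as a covariate.

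Averaged over both layers, mutants had higher levels than WT of Slc17a8 (1.19 ± 0.17, adjusted p = 0.00808) and Cort (1.11 ± 0.18). This contrast is the mean of the 2 layer differences, so SPI alone can carry it, and SPE vs WT had 0 calls. Cort ranged from 5.12 to 5.42 in WT, 4.96 to 5.62 in SPE and 6.78 to 8.19 in SPI. Slc17a8 ranged from 6.28 to 6.78, 6.36 to 7.18 and 8.33 to 9.00 in the same order. Further rises were in S100a13 (1.07 ± 0.18), the troponin gene Tnnt1 (1.03 ± 0.23), Matn4 (1.03 ± 0.20), the glutathione transferase Gstk1 (1.02 ± 0.17), the growth factor Igf2 (1.01 ± 0.21) and Scrg1 (1.01 ± 0.15). The largest falls were in Tspan3 (-1.68 ± 0.43), Tceal3 (-1.60 ± 0.35), Atp5pb (-1.57 ± 0.36), Rbm3 (-1.39 ± 0.31), Tspyl1 (-1.23 ± 0.30), the G protein gene Gnas (-1.20 ± 0.31), the calpain subunit Capns1 (-1.15 ± 0.29) and Elmod1 (-1.14 ± 0.29). Of astrocyte markers 6 of 19 rose (median 0.35, camera adjusted p = 5.42e-06), of microglia markers 6 of 15 (median 0.54, 5.42e-06) and of myelin markers 8 of 22 (median 0.54, 1.51e-05), and for all 3 lists the adjusted p was 0.353 with an estimated correlation. Interneuron markers stood higher (median 0.33, 3 of 15 rose) and glutamate receptor genes lower (median -0.13, 0 of 28 called), both at a camera adjusted p of 0.0498, with adjusted p = 0.395 and 0.353 under an estimated correlation. Adjusted over the list alone, rises numbered 9, 9, 13 and 6 for astrocyte, microglia, myelin and interneuron markers, and 1 interneuron marker fell.

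Limma called 296 features in KO vs WT, 186 higher and 110 lower, with 25 beyond 2-fold. With each animal's layers averaged, 5 mutants against 5 WT mice, limma called 0 (1771 at an unadjusted p under 0.05). The mutant without an SPI array entered that fit with its SPE array alone, not with a mean of both layers. The fit on animal means is therefore not quite the same contrast, and how far that mutant widened the spread was not tested. With the mean signal as a covariate limma also called 0 (1487 at an unadjusted p under 0.05). None of the calls of this comparison held in either fit. The count was 507 without the animal block, 487 without background correction, 490 with the deposited normalised values, 446 over all probes (211 higher, 235 lower), 229 with median scaling (169 higher, 60 lower) and 1097 with array weights. It was 34 without WT 206, 59 without WT 145, 61 without WT 142, 70 without WT 144, 98 without WT 199, 96 without SPE 147, 147 without SPE 146, 105 without SPE 166, 147 without SPI 146 and 749 without SPI 166.

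Differences from WT in the 2 layers were correlated across genes (r = 0.58), but both used the same WT arrays, and unchanged layers simulated against those arrays gave a mean r of 0.63 (0.60 to 0.64 in 100 simulations). The covariance was 0.0499 against 0.0208 in the simulations (0.0196 to 0.0222). With the WT arrays divided between the layers the mean r over 20 divisions was 0.41 (0.25 to 0.54). Genes are not independent replicates in these values. As SPE vs WT had 0 calls, 0 genes were called in both layers, and 0 would be so in independent lists. Of the 206 features higher in SPE at an unadjusted p under 0.05, 100 were called higher in SPI, where independent lists would share 28.0, and of 152 lower ones 85 were called lower, against 16.5. Neither reference value includes both the shared WT arrays and the real changes. The simulations carried a single consensus correlation of 0.319 between layers of a mouse, while the 4 mice with both layers ranged from 0.119 to 0.631. The divided WT arrays and the independent lists do not allow for these shared animals. Part of the r with divided WT arrays, and of the excess over independent lists, may come from them.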

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

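The tests of low signal, of probes of a gene, of endothelial markers and of the outer layer's markers were chosen after the results they bear on were seen, as were the fits without the dimmest arrays and with the mean signal as a covariate; the simulated power and the counts over other splits of the arrays were planned.

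Some values lay far from the rest of their group by a gap test that chance passes in about 1 of 20 groups: 0 of 6 groups of array measures, 2 of 39 of list scores and 39 of 297 of the named genes. Most of them were genes on SPE 148, the dimmest SPE array. There the lower values were those of Tspan3 (7.91), Tceal3 (6.92), Atp5pb (8.73), Selenof (8.38), Hnrnpa2b1 (5.87), Rbm3 (7.29), Ube2e3 (5.83), Tsc22d1 (5.10), Gosr2 (6.80), Kdelr2 (4.50), Cox7a2l (8.56), Pdhb (7.69), Vdac3 (8.40), Cpne4 (11.81), Itm2a (5.96), Efr3a (5.64), Gnas (7.87), Capns1 (8.45) and Elmod1 (6.52). Higher values on SPE 148 were those of Matn4 (6.41), Erich5 (7.71), St18 (5.74), Tpst2 (9.78), Dclk2 (10.44), Rpl36a (11.55), S100a13 (7.73) and Ier3 (8.41). Other arrays stood out for Cpne4 on WT 145 (12.63), Laptm5 (7.04) and Igf2 (6.42) on WT 206, Kif2a (7.32), Itm2a (6.14) and Cbln1 (5.93) on WT 199, Tmem119 (5.42) and Ybx3 (4.99) on WT 144, Rpl37 on SPE 166 (12.68), and Pvalb (11.99), Vtn (7.88) and Igf2 (8.29) on SPI 166. The interneuron marker score of WT 144 (0.15) and the complex I score of SPE 166 (-0.16) stood out among the lists.

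The differences from WT differed between the layers for 1917 features (1768 of them named genes) and for 7 lists, by limma and camera on the contrast between layers. The list medians of that contrast were 1.13 for interneuron, 0.66 for astrocyte, 0.89 for myelin and oligodendrocyte, 0.82 for oligodendrocyte precursor, 0.63 for microglia and 0.64 for thalamic markers, and 0.23 for the cytosolic ribosome. With an estimated correlation none of the list calls held.

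The 1016 features lower in SPI than in WT had a median difference of -0.75. Low signal on the SPI arrays may account for much of it: the slope of each gene on log2 mean signal within WT and SPE predicted a median of -0.51 (interquartile range -0.83 to -0.25), although this rested mostly on SPE 148, without which the prediction was -0.067 (-0.39 to 0.24). Low signal bears on the rises too. For the 1273 higher features, with a median difference of 0.62, the same slope predicted 0.33 (0.15 to 0.53). Without SPE 148 that prediction was 0.092 (-0.18 to 0.37). Loss that differs between probes of a gene cannot be told apart from loss shared by them: over the 276 lower genes with further probes, these lay 0.20 (interquartile range -0.12 to 0.60) above the brightest probe's difference and had the same sign for 87.0%, but the genes had been called on the brightest probe, which alone widens that gap, and over all 2085 genes with further probes the gap was -0.23. Further probes lay -0.25 from brightest probes of similar level, so their fall in SPI was not one of level alone. A change in the inner layer's cells stays open beside both.

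The members of the 5 glial and interneuron lists had a median of 0.81 above WT in SPI. Low signal as the whole cause is argued against by size, since the median was 0.91 with mean signal as a covariate and 0.89 without the 3 dimmest arrays. Camera's highest adjusted p of the 5 lists, at the preset correlation, was then 0.000151 and 4.75e-05. With an estimated correlation the main fit gave camera adjusted p from 0.221 to 0.244, so its list calls did not hold. The covariate fit and the fit without the 3 dimmest arrays were not run with an estimated correlation. Neither fit removes the signal gap. Mean signal was lower in SPI, and SPI 146 (362) and SPI 166 (331) stayed below the dimmest WT array (371). Low signal as a part of the cause stays open. Whether a lower share of pyramidal cells raised every other type alike cannot be decided here. The 5 lists were singled out because they passed camera in these data, and the endothelial list had not, which favours a gap in advance. With the 1 gene on both sides left out, the 19 endothelial and mural markers had a median of 0.30. It lay -0.52 from that of the remaining 77 genes of the 5 lists, 0.82. Per array that gap was -0.95, -0.54, -0.33 and -0.47 on SPI 147, 146, 166 and 148, a mean of -0.59 from WT. An exact permutation over arrays gave p = 0.00794, and without SPI 147 the mean was -0.47 with p = 0.0179, each the smallest possible. Leaving out SPI 147 raised the mean endothelial value from 0.31 to 0.46. These p-values carry the same selection of lists, and levels were centred on the WT arrays, which holds those near 0. A sampling of WT CA3 that spans what is divided in mutants cannot be told apart from an effect of the genotype, because WT tissue was not divided; the same genes had a median of 0.023 in SPE (95% bootstrap interval -0.039 to 0.079), and whether more of these cells lie in or beside the inner layer was not tested.

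Limma called 0 genes in SPE vs WT, with 358 at an unadjusted p under 0.05 where 468 would be expected by chance. The main fit shares 1 estimate of spread over the 3 groups, the SPI arrays among them. With the SPE and WT arrays alone that number was 826, with array weights 722 and with median scaling 205, each with 0 calls. Too few arrays is argued against as the cause for 2-fold changes in many genes, since 84.3% of 134 simulated ones were called. Changes of 0.5 on the log2 scale were called for 14.9% and could have been missed. The same draws held changes of 2 on the log2 scale, and 2-fold changes in only a few genes were not simulated.

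Chance was tested by fits without the block on other splits of the same arrays, 100 drawn of 126 per comparison with the real one included. For SPI vs WT 1 of 100 splits, the real one itself, called as many features (1709, highest other 0), which argues against chance but does not exclude it. For SPE vs WT (0 real, highest other 1) and for KO vs WT on animal means (0 real, highest other 0) all 100 splits did, which a real count of 0 fixes in advance, so this says nothing about chance. For SPI vs SPE 3 of 100 splits called as many (452 real), but these splits ignore that 4 mice gave both layers, so they leave chance undecided. The highest other split, with SPE 148 moved to the SPI arrays, called 893, a structure of the arrays. With the animal block, the real split called 1109 features and the highest of the others that part all 4 pairs called 1, but these 16 splits are too few for a share under 0.05.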

How the results depend on the processing

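The fits with the mean signal as a covariate, without the 3 dimmest arrays and without animal 148 were chosen after the data were seen; the others were planned. The cause of the differences below was not tested, except that smaller fits have fewer arrays. SPE vs WT had 0 calls under every alternative run. The SPI vs WT count stayed within 1.5 times its value of 2289 except at 503 with the covariate, of which 404 were among the 2289, and ran from 1613 to 2615 as arrays were left out. Median scaling called 3191 features there, but 1326 of the 2289 were among them. The KO vs WT count of 296 became 487 without background correction, 490 with the deposited normalised values, 446 over all probes, 1097 with array weights, 760 without the 3 dimmest arrays, 0 on animal means and 0 with the covariate. On animal means the mutant without an SPI array entered with its SPE array alone. Leaving out 1 array gave 34 (WT 206) to 749 (SPI 166), with 59 (WT 145), 61 (WT 142), 70 (WT 144), 98 (WT 199), 96 (SPE 147), 147 (SPE 146), 105 (SPE 166) and 147 (SPI 146) also beyond 1.5 times. The SPI vs SPE count of 1917 became 452 in the 2-group fit, 1175 without the 3 dimmest arrays, 781 with the covariate, and 946 (SPI 148) to 2217 (SPI 166) as arrays were left out. Without the animal block, calls numbered 507 in KO vs WT and 1065 in SPI vs SPE, and with the animal as a fixed block 356 in SPI vs SPE; of the other results, dropping the block ended only the call of Dclk1 in SPI vs WT. The correlation of the layers' differences fell from 0.58 to 0.41 with the WT arrays divided. Among values that changed sign only Nos1 in SPI had been called (0.11 with median scaling). The others were Dcx in SPI (0.21, median scaling), Dclk3 in SPE (-0.12 to 0.10 as arrays were left out, -0.037 with the covariate), Uty in SPI (0.40 with median scaling, 0.11 with the covariate), Uty in SPE (0.0027 without background correction, 0.042 with median scaling, 0.0023 with the deposited values, 0.077 with the covariate, -0.11 to 0.076 as arrays were left out) and Eif2s3y in SPI (-0.28 to 0.65 as arrays were left out, -0.30 without animal 148). Of the list calls, each was lost with camera's estimated correlation. A chip term was not run, since no file names the chip. Signal over background limits SPI 147, SPE 148 and SPI 148 most, with 8413, 10123 and 10366 probes detected against 11303 to 11988 on WT arrays.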

Other observations

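The values in the first paragraphs come from the planned fit, and no test here was chosen after its result was seen apart from the fits with the mean signal as a covariate, without the 3 dimmest arrays and without animal 148. Some synaptic and stress genes were called in SPI vs WT, in both directions, and none of their lists passed camera. Of 28 genes of glutamate receptors and the postsynaptic density 3 rose and 6 fell in SPI, among them the AMPA receptor subunit Gria2 (-0.59 ± 0.13 SE, n = 4 and 5) and its auxiliary subunit Cacng3 (-1.41 ± 0.27), with a list median of -0.18 (adjusted p = 0.132 with camera and 0.0230 with fry, lower). Of 34 synaptic vesicle genes 3 rose and 7 fell (median -0.13, adjusted p = 0.265), and of 11 genes of GABA receptors and transport 2 rose and 2 fell (median -0.14, adjusted p = 0.626). Among 18 genes of the unfolded protein response 3 rose and 3 fell, the latter being the chaperones Calr (-1.38 ± 0.36) and Pdia3 (-0.72 ± 0.18) and Creld2 (-1.18 ± 0.28), with a median of 0.034, a mean of -0.17 and a camera adjusted p of 0.545. All 5 of these genes lost their call with the mean signal as a covariate, Cacng3 also with median scaling, Calr and Pdia3 also without the 3 dimmest arrays, and Creld2 also with probes detected on all 14 arrays.

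Immediate early genes gave 4 rises and 0 falls among 22 in SPI (median 0.051, camera adjusted p = 0.626), with Ier3 at 0.92 ± 0.20, Gadd45g at 0.73 ± 0.19 and the phosphatase Dusp1 at 0.68 ± 0.16. The interferon-induced genes Ifitm3 (0.79 ± 0.15) and Ifit3 (0.67 ± 0.17) were the 2 of 12 reactive gliosis genes that rose (median 0.26, adjusted p = 0.414 with camera and 0.0414 with fry, higher). Calls of these 5 genes were lost with the mean signal as a covariate, those of Gadd45g and Dusp1 with median scaling and that of Gadd45g without the 3 dimmest arrays, while the other probe of Gadd45g had the opposite sign. Rgs5, on the list of CA2 pyramidal markers and also known from pericytes, rose by 1.23 ± 0.27, and 2 of the 6 CA2 markers rose (median 0.30, adjusted p = 0.478). Glycolysis (2 rises and 4 falls among 16), lysosome and autophagy (6 and 7 among 50), heat shock (2 and 1 among 18), cholesterol synthesis (0 and 2 among 17), immature neuron markers (4 and 3 among 18), neuropeptides (4 and 3 among 20) and axon guidance (8 and 6 among 53) did not pass camera as lists, with adjusted p from 0.344 to 0.835. Of these, fry passed immature neuron markers (0.00794) and neuropeptides (0.0199) as higher. Nor did the markers of dentate granule cells (1 rise among 4), mossy cells (0 of 4 called), choroid plexus (1 rise among 5) or thalamus (1 rise among 6), with camera adjusted p from 0.265 to 0.714, while fry passed those of choroid plexus (0.0200) and thalamus (0.000671) as higher. Blood markers (3 measured) were too few to be tested as a list.

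Animal 148 stood apart in both layers. Its layers deviated together from their groups with r = 0.631, against 0.119 to 0.323 in the other 3 mice with both layers. SPE 148 had a mean signal of 279 and SPI 148 one of 231. The consensus correlation between layers of a mouse was 0.319 with all arrays, 0.0400 without animal 148, 0.541 without SPE 147 and 0.493 without SPI 147, so this estimate rested on single mice in both directions.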
